A study of Mus musculus with 3 samples.

How the data were processed

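Chromatin bound to the long non-coding RNA Pvt1 was recovered from C2C12 cells, a mouse myoblast line, by hybridising biotinylated DNA oligonucleotides to the RNA (chromatin isolation by RNA purification, ChIRP). Per the labels' protocols, cells were fixed with 1% glutaraldehyde for 15 min, chromatin was sheared to fragments of 50 to 130 bp, and 400 pmol of probes were added. The 18 probes of 20 bases were split into an odd and an even set of 9 each. The series holds 3 samples: 1 precipitated with odd probes, 1 with even probes, and 1 of unprecipitated DNA with a mean fragment length of 400 bp. The design text speaks of separate biological samples, while the titles of both precipitated samples carry replicate number 1. With 1 sample per probe set there were no replicates within a set, and no value below has a replicate error.

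Libraries were sequenced on an Ion Torrent instrument and aligned to mm10, the GRCm38 assembly, per the labels' protocols. The authors called peaks separately for each probe set with MACS2 version 2.1 against the unprecipitated DNA. Per the file headers, tags were extended to 147 bp without a fragment model, the q-value cutoff was 0.05, and 1 tag was kept per position. Per the file headers, the effective genome size was 90000000, which is the preset of the caller for a nematode and not the one for mouse. The design text names default settings, which differs from the headers.

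Per the file headers, the odd library had 1310893 tags with a tag size of 105 bp, of which 14203 (1.08%) remained after duplicates were removed. The even library had 1352067 tags with a tag size of 54 bp, of which 12715 (0.940%) remained. The unprecipitated library had 5375267 tags, of which 5104779 (95.0%) remained. Each peak therefore rests on few tags, with a median pileup of 4 at the summit in both lists.

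The deposited lists give, per peak, its position, the pileup (a signal in extended tags at the summit), and the −log10 of the p and of the q value. They also give the fold enrichment, a ratio of pileup to a background computed by the authors' caller. The p and q columns have a spreadsheet error as their header and were read from their place in the caller's output. The ratio equalled (pileup + 1) / (1 + background) to within 1e-04 for 961 of 962 odd peaks and 706 of 714 even peaks, with a uniform background of 0.0232 and 0.0208 tags. A fold enrichment thus restates the pileup for nearly all peaks, and was used here to rank and describe peaks within a list. The lowest pileup of a listed peak was 3 tags in the odd list and 2 in the even list.

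Positions were used as deposited, and all peaks lay within the chromosomes of the GRCm38 reference. Genes came from GENCODE mouse release 21, with 55413 genes on the main chromosomes, 21938 of them protein-coding. A promoter was the 2000 bp upstream of the annotated start of a gene, the window named in the study's design text, and a peak counted with an overlap of at least 1 bp. Peaks were assigned to annotation classes by their centre, in the order promoter, exon, intron and intergenic. A total of 11 gene lists with 274 genes were written before the data were examined, and all 274 symbols were found in the annotation.

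Each comparison was tested by permutation of positions, placing the peaks of a list at random outside assembly gaps, 100000 times for the reported values and 10000 times for alternatives. The mean match to the probes of the own set was compared with 100 shuffles. Shuffles stayed within the chromosome of each peak, except for the counts per chromosome and around Pvt1, which used the whole genome. Overlap, shared promoter genes and the Pvt1 region were tested one-sided, the others two-sided. Counts per chromosome (42 tests), annotation classes (8 tests) and gene lists (22 tests) were adjusted by the Benjamini-Hochberg method. The smallest p that 100000 shuffles can give is 1e-05. These tests take peaks as independent placements, so they compare the lists with random positions and carry no information on variation between cell cultures.

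The genes named were chosen by a rule set before the data were examined. It takes Pvt1 and Myc; the 15 genes with promoter peaks in both lists and the highest lower fold enrichment; the 10 protein-coding promoter genes per list with the highest fold, leaving out those with a provisional name such as a Gm number; members of the gene lists with a promoter peak, and up to 4 per list with a peak in the gene; and the 5 shared peaks with the highest lower fold. Ties were broken by name.

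The alternatives set in advance were promoters of 1000 or 5000 bp, 500 bp added downstream, protein-coding genes only, overlap of at least 50% of each peak, a gap of up to 500 bp, a q-value of at most 0.01, the better-scoring 50% of each list, removal of peaks over 50% soft-masked, autosomes and X only, genome-wide shuffles, and shuffles matched on repeat class and on GC within 5 percentage points. Because many peaks tie in fold enrichment, the better-scoring 50% kept every peak at or above the median. One alternative was added after seeing the data: it leaves out peaks with a probe match of at least 12 bases or with a recurring 8-base sequence at an edge. Edges were read inward as 50 bp starting 10 bp outside each end of a peak. The left edge was read on the plus strand and the right edge on the minus strand. The 20 8-base sequences most over-represented in the 504 unshared odd peaks against 20000 random positions were picked, and then counted in the even list. This step was set up after the data were examined. Similarity to the probes, also added later, was the longest exact match and the most bases matched without gaps to any probe of either set; a peak was no more similar than the median shuffled position at 8 or fewer and 13 or fewer bases.

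The shuffle tests were tested on simulated data with 1000 shuffles. Of 100 random lists of 714 positions, 7 were called for promoters, and all 100 were called once 31 positions were moved into promoters. For the overlap with odd peaks, 0 of 100 random lists were called, and all 100 were called with 10 planted overlaps. For the edge sequences, 20 runs on random positions gave a median of 5.29% of held-out positions, against 5.57% in the background. A sequence planted in 33.3% of positions was recovered in a median of 34.5%. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.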

Results

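Peaks of DNA recovered with the long non-coding RNA Pvt1 were compared between 2 sets of capture probes in C2C12 mouse myoblasts. The list for the odd probes held 962 peaks and the list for the even probes 714. Peaks were short and shallow in both lists, with a median length of 148 bp and a median pileup of 4 tags. The pileup at the summit reached 22 tags with odd probes and 20 with even probes. Peaks of 3 tags made up 49.0% of the odd list and 45.2% of the even list. There was 1 sample per probe set, so the comparisons below set peak positions against shuffled positions.

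The first question was whether DNA at the Pvt1 gene itself was recovered. Pvt1 (ENSMUSG00000097039.8) is annotated on the plus strand of chromosome 15 from 62037986 to 62378096 in GRCm38, next to the Myc oncogene. Each list had 8 peaks inside the gene, and all 8 touched an annotated exon in both lists. The highest peak of each whole list lay here, at 62250661 to 62250948, with a fold enrichment of 22.5 (odd) and 20.6 (even). A second exon region, 62249569 to 62250381, formed the longest peak of the odd list at 813 bp, with a fold enrichment of 16.6. The even peak there was 811 bp long with a fold enrichment of 9.80. The peak over the first exon, 62037974 to 62038124 with odd probes, had 7 tags in both lists. Myc (ENSMUSG00000022346.15, 61985391 to 61990374) carried no peak, and the nearest peak in both lists was that at the Pvt1 first exon, 47600 bp away.

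Within Pvt1 and 1 Mb on each side, 10 peaks were found in each list. Shuffled positions gave a mean of 0.847 peaks for the odd list and 0.628 for the even list (one-sided permutation p = 1e-05 for both, the smallest possible). The peaks covered 0.697% of the gene with odd probes and 0.630% with even probes. All 8 peaks inside the gene overlapped a probe site in each list. Of the 9 odd probes, 9 were covered by an odd peak and 8 by an even peak. Of the 8 even probes with a full match in the region, 7 were covered by a peak in each list. The odd probe AGACTTAGGGCATACAGGTA, at 62250790 to 62250809, and the even probe TAAAGCATCCAGGGCAGAAC, at 62250921 to 62250940, both lay in an exon under the highest peak of each list. The even probe AGAATTTCAGAGGGCACTCG, at 62250463 to 62250482, had no peak in either list. The median distance from the right end of a Pvt1 peak to the nearest probe 5′ end was 5 bp in the odd list and 7 bp in the even list. No peak within 1 Mb of Pvt1 was left once peaks with a probe match or a recurring edge sequence were removed, a setting chosen after seeing the data.

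**Figure D1:**
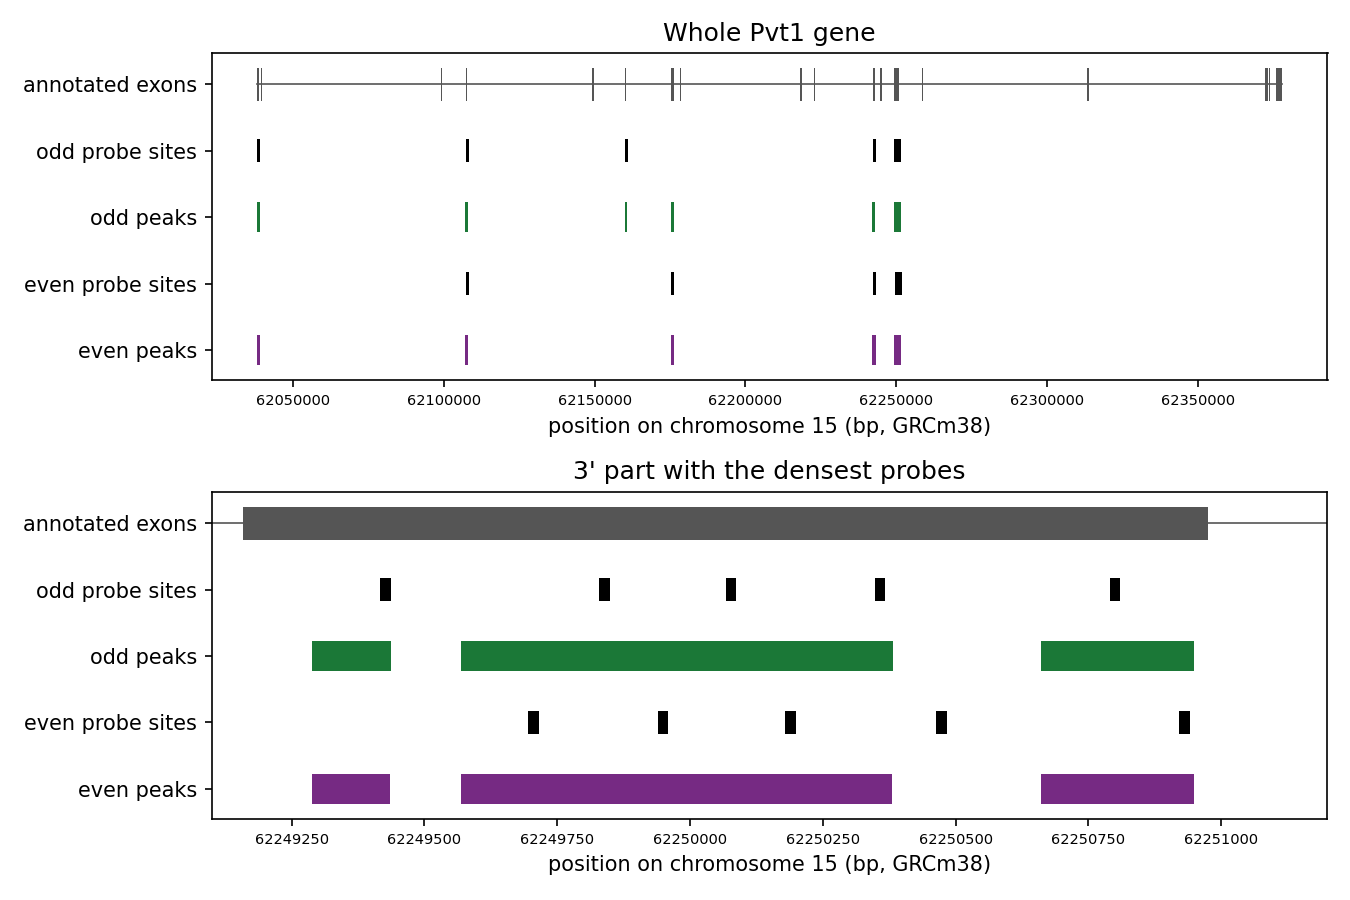
Annotated Pvt1 exons (grey), probe sites (black) and peaks of the odd (green) and even (purple) lists along chromosome 15 in bp, for the whole gene and for the exon with the densest probes. The narrowest marks are widened to stay visible. All 8 peaks of each list overlap a probe site, and odd and even peaks lie at nearly the same positions.

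The second question was whether peaks of the odd and even probes, which target different sites of the RNA, lay at the same places. Many did: 459 of 714 even peaks (64.3%) overlapped an odd peak, and 458 of 962 odd peaks (47.6%) overlapped an even peak. Overlap alone does not show that each probe set recovered a place independently. Shuffled even peaks overlapped an odd peak 0.0806 times on average and at most 3 times (one-sided permutation p = 1e-05, the smallest possible). Outside Pvt1, the highest shared peak lay on chromosome 1 at 141647923 to 141648081, between genes, with a fold enrichment of 14.7 in both lists. Further high shared peaks lay in an intron of Unc5d, a netrin receptor gene (chromosome 8, 29172774 to 29172936, fold enrichment 15.6 odd and 13.7 even). Another lay in an intron of Stag1, which encodes a cohesin subunit (chromosome 9, 100831209 to 100831373, 13.7 and 15.7). With the Pvt1 peaks at 62250661 to 62250948 (22.5 and 20.6) and 62242104 to 62242493 (13.7 and 12.7), these were the 5 shared peaks with the highest lower fold. The 3 outside Pvt1 each carried a recurring edge sequence. Without peaks with a probe match or such a sequence, 34 of 117 even peaks (29.1%) overlapped an odd peak, a setting chosen after seeing the data.

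Overlapping odd and even peaks started at nearly the same base. The median difference of starts over 459 pairs was 1 bp, 203 pairs started at the same base and 406 (88.5%) within 2 bp. Overlaps placed at random within the tag extension would start within 2 bp in 1.70% of cases. Peak length followed the pileup: 72.7% of odd peaks and 69.7% of even peaks with 4 or more tags had exactly the length that tags at consecutive bases give. Shared peaks were higher than unshared ones. Their median fold enrichment was 5.86 against 3.91 in the odd list (458 and 504 peaks, two-sided permutation p = 1e-05, the smallest possible). It was 4.90 against 3.92 in the even list (459 and 255 peaks, permutation p = 0.0322). The even difference no longer passed the threshold without peaks over 50% soft-masked (permutation p = 0.0664), although the median difference stayed at 0.980 and the means were 5.60 and 4.38. The odd difference was 0.977 and did not pass without peaks carrying a probe match or a recurring edge sequence (34 and 83 peaks, permutation p = 0.0680). There the even medians differed by 0.490 (permutation p = 0.0460), with means of 4.75 in shared and 4.79 in unshared peaks. A place with few tags is less likely to pass the cutoff in both lists, whatever the cause. The difference in height therefore does not show why peaks were shared.

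**Figure D2:**
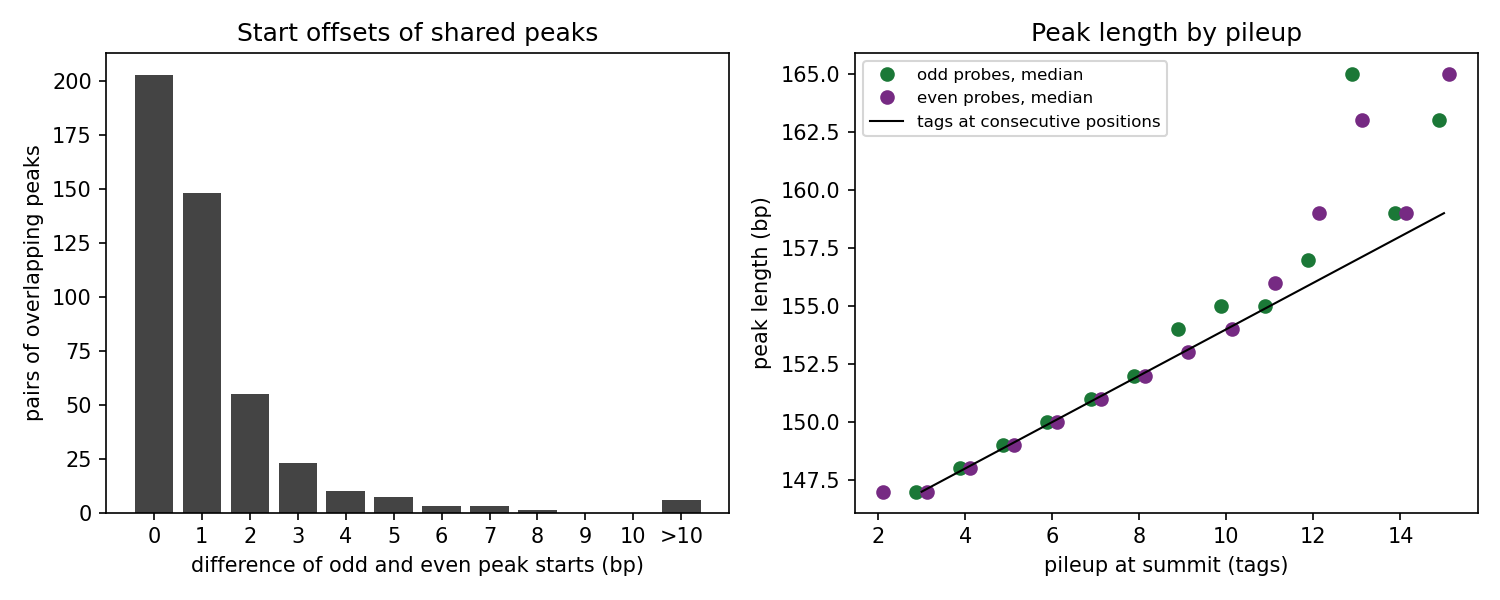
Left, number of pairs of overlapping odd and even peaks by the absolute difference of their starts in bp. Right, median peak length in bp against pileup at the summit in tags, up to 15 tags, for odd (green) and even (purple) peaks, with a line for tags at consecutive positions. A total of 203 pairs start at the same base, and the medians follow the line at low pileup.

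Peak edges carried recurring 8-base sequences. ATTTCCCC stood at an edge of 169 of the 504 unshared odd peaks and of 43 of the 255 unshared even peaks, against 0.220% of random positions. TTTTGGGG stood at 51 and 37 of them. Of the unshared even peaks, which played no part in picking the 20 sequences, 169 (66.3%, Wilson 95% interval 60.3 to 71.8) had at least 1 of the 20. Random positions had one in 3.55% of cases, and positions matched to even peaks in GC and repeat class in 3.38%. Among shared peaks the share was 88.6% in the odd list and 88.7% in the even list.

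The third question, taken from the study's own criterion, was which genes had a peak in the 2000 bp upstream of their start. Promoter peaks were found for 51 genes with odd probes and 53 with even probes, and 29 genes had one in both lists, 12 of them protein-coding. Shuffled even peaks gave 0.0318 shared genes on average (one-sided permutation p = 1e-05, the smallest possible). The odd and even peaks overlapped each other at all 29 genes, which rested on 25 distinct odd peaks. The highest was Commd8, a COMM domain gene (chromosome 5, odd peak 72168315 to 72168478), with a fold enrichment of 12.7 and 17.6 and the peak centre 207 and 206 bp upstream of the start. Ubfd1 followed (chromosome 7, 122066969 to 122067122, fold enrichment 9.77 and 11.8), with a peak that also lay in an exon of Ears2. Vps29, which encodes a retromer subunit, had 11.7 and 8.82 at 122353845 to 122353999 on chromosome 5, also in an exon of Rad9b. Tbc1d14, a regulator of autophagy, had 7 tags in both lists (chromosome 5, 36593447 to 36593597), also in an intron of Gm42936. The peaks at Commd8, Ubfd1, Vps29 and Tbc1d14 each carried a recurring edge sequence.

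Col6a4, a collagen VI chain gene, had a fold enrichment of 8.80 with odd probes and 5.88 with even probes. The nucleoporin gene Nup214 had 5.86 and 5.88. The peak at Col6a4 also lay in an exon of Gm36993, and that at Nup214 in an exon of Aif1l. Among non-coding genes, Gm26901 had 9.77 and 7.84 and A730020E08Rik had 7.82 and 6.86. Mir192 and Mir194-2, a pair of neighbouring microRNA genes, shared a peak of 5 tags in both lists on chromosome 19. Gm29797 had 6.84 and 5.88, and Gm15038 had 6.84 and 4.90. Pvt1, Gm27913 and Gm27718 were also among these genes, and 4 of the 29 genes, Pvt1 included, lie within Pvt1. Promoter peaks in the odd list alone included Ptpn13, a tyrosine phosphatase gene (6 tags), and Mocos (5 tags). Those in the even list alone included Fam177a (5 tags), Csf1r, the receptor of a macrophage growth factor (4 tags), Extl3 (4 tags) and Krt7 (4 tags). Cfap52 and Rnf180 had 5 tags with odd probes and 3 with even probes. Of the 29 shared genes, 20 had a recurring edge sequence at the odd peak, 6 a probe match and 3 neither. Those with neither were Gm29797, Gm21960 and Terc, and the last 2 shared the same peak on chromosome 3. Without peaks carrying an edge sequence or a probe match, 3 shared genes were left of 9 odd and 17 even ones.

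Promoters as a class held more even peaks than shuffled positions. They held 47 of the 714 even peaks (6.58%) against a mean of 30.6 ± 5.40 (SD of 100000 shuffles), a ratio of 1.54 (two-sided permutation p = 0.00522). For odd peaks the count was 46 of 962 (4.78%) against 41.4 ± 6.30, a ratio of 1.11 (permutation p = 0.504). The difference between the lists was not tested. With promoters of 5000 bp the even ratio was 1.17 (permutation p = 0.154), and in the better-scoring 50% of the odd list the odd ratio was 1.60 (p = 0.0140). A setting chosen after seeing the data left out peaks with a probe match or a recurring edge sequence. Promoters then held 14 of 117 even peaks (ratio 2.74, permutation p = 0.0020) and 8 of 117 odd peaks (ratio 1.56, permutation p = 0.290).

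Peak centres lay in introns more often and between genes less often than shuffled positions in the odd list. Introns held 433 of 962 odd peaks (45.01%) against 41.1% (ratio 1.10, adjusted permutation p = 0.0362), and intergenic sequence 44.9% against 50.3% (ratio 0.893, adjusted p = 0.00480). Intergenic sequence held 45.2% of even peaks against 50.3% (ratio 0.900, adjusted permutation p = 0.0290). Exons held 5.72% of odd and 4.90% of even peaks (adjusted permutation p = 0.172 and 0.769), and introns 44.1% of even peaks (adjusted p = 0.172). Promoters by peak centre held 4.37% of odd and 5.74% of even peaks (adjusted permutation p = 0.719 and 0.0586). None of the 8 tests passed with positions matched in GC and repeat class, with protein-coding genes only, or in the better-scoring 50% of each list.

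Peak numbers differed from shuffled positions on chromosomes 18 and Y, with 3 of 42 tests past the threshold. Chromosome 18 had 52 odd peaks against a shuffled mean of 31.8 (ratio 1.64, adjusted permutation p = 0.0137); the even list had 32 there (ratio 1.36, adjusted p = 0.644). Chromosome Y had 12 odd and 7 even peaks, against 32.03 and 23.8 (ratio 0.375 and 0.294, adjusted permutation p = 0.00210 for both). The labels used here do not state the sex of the cell line, and whether the tags on Y were misaligned was not tested. If the line is female, as C2C12 is believed to be, the peaks on Y are misalignments and the counts and ratios there describe alignment alone. Chromosome X had 39 odd peaks (ratio 0.656, adjusted permutation p = 0.0609) and 29 even peaks (ratio 0.658, adjusted p = 0.142). Chromosome 15, which holds Pvt1, had 45 odd peaks (ratio 1.23) and 32 even peaks (ratio 1.18). In the better-scoring 50% of each list 0 chromosome tests passed, as was the case without peaks with a probe match or recurring edge sequence. Without peaks over 50% soft-masked 5 tests passed, with chromosome X added in both lists. Shuffled positions there still included soft-masked sequence, so they differed from the kept peaks in repeat content.

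**Figure D3:**
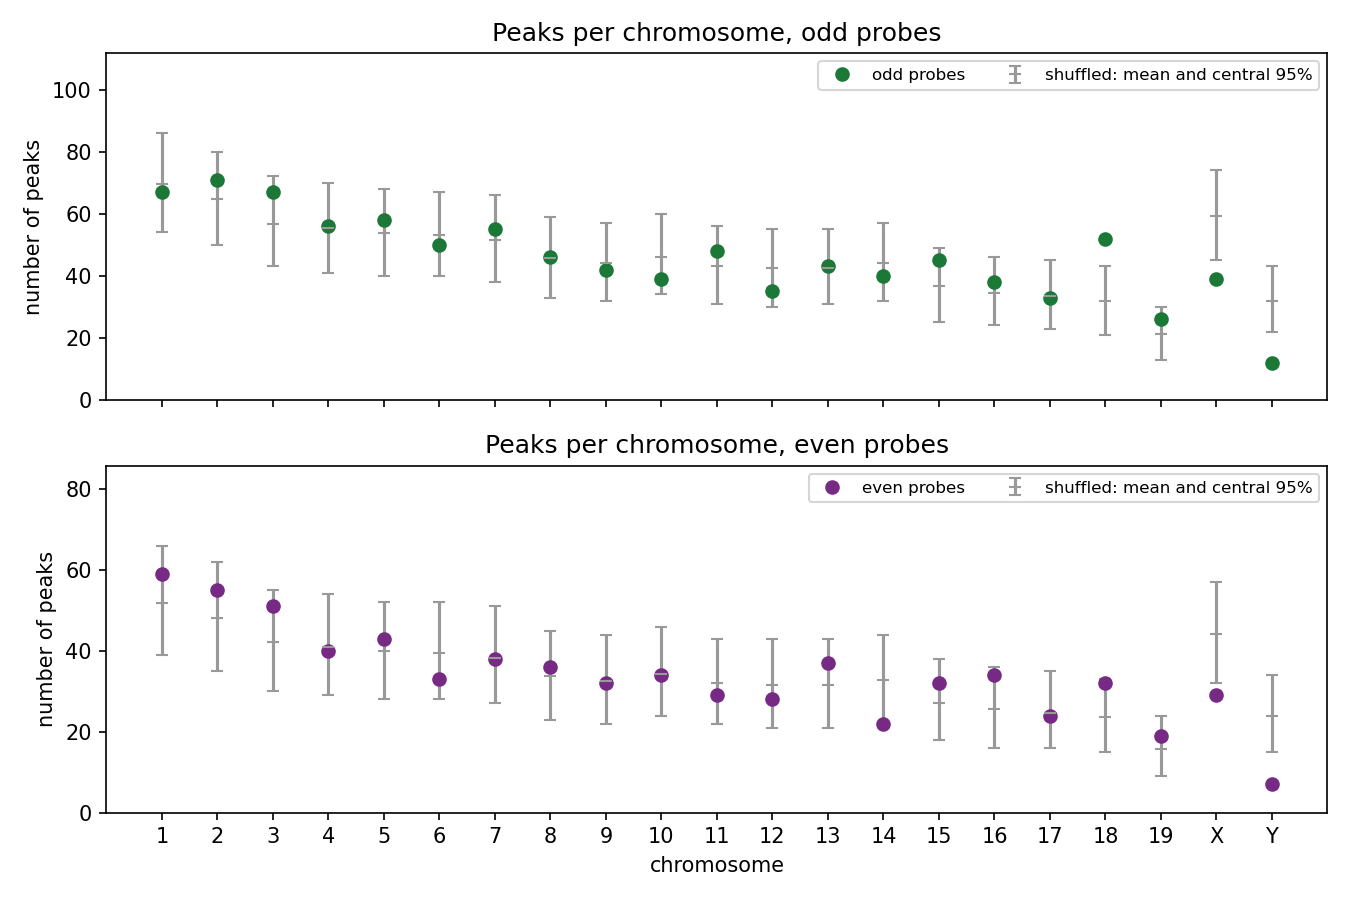
Number of peaks per chromosome for odd (green) and even (purple) probes, with the mean and central 95% of 100000 genome-wide shuffles in grey. Chromosome 18 lies above the shuffled range in the odd list with 52 peaks, and chromosome Y lies below it in both lists with 12 and 7.

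None of the 11 gene lists had more or fewer members with a peak than shuffled positions after adjustment, and 0 of 22 tests had an unadjusted p under 0.05. A total of 11 of 274 listed genes had an odd peak in the gene or its 2000 bp upstream and 8 had an even peak, and 0 had a promoter peak in either list. Each of the peaks named below carried a recurring edge sequence, except those at Apc and Ccnd3, which were the members left without peaks with a probe match or such a sequence. Among muscle atrophy and FoxO signalling genes, Igf1r, the receptor of an insulin-like growth factor, had 8 tags in both lists at 68032991 to 68033142 on chromosome 7. The transcription factor gene Runx1 had peaks of 5 tags in both lists, and Foxo3 a peak of 3 tags in the odd list. These 3 odd genes compared with a shuffled mean of 0.740 (permutation p = 0.0690, adjusted p = 0.759), and the 2 even genes with 0.571 (adjusted p = 1).

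In the Myc network and cell cycle list, Max, which encodes the dimerisation partner of Myc, had an even peak of 5 tags 669 bp inside the gene, and Ccnd3, a D-type cyclin gene, one of 3 tags. The odd list had 0 members, and the even count of 2 compared with 0.254 (permutation p = 0.0504, adjusted p = 0.759). Among TGF-beta and Wnt signalling genes, Apc (4 tags) and Lrp5 (3 tags) had odd peaks and Tcf7l2 (3 tags) an even peak. Among polycomb and chromatin regulators, the acetyltransferase gene Crebbp had a shared peak of 3 odd and 5 even tags on chromosome 16, and Jarid2 an odd peak of 3 tags. Neuronal synapse genes, which are not muscle genes, had 4 members with an odd peak (Nrxn3, Cntnap2, Dlg2 and Grin2a) and 2 with an even peak (Nrxn3 and Cntnap2), against 3.89 and 2.96 in shuffled positions (adjusted permutation p = 1 for both). The lists of myogenic regulators, mitochondrial dynamics and mitophagy, apoptosis and Bcl2 family, autophagy, respiratory chain subunits and hepatocyte genes had 0 members with a peak in either list. At this depth a count of 0 was not distinguishable from chance, since shuffled means for these 6 lists lay under 1 gene.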

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

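The alternative without peaks carrying a probe match or a recurring edge sequence was chosen after seeing the data, and all others before. Of 70 settings fixed in advance over 11 results, 62 kept their direction and side of the threshold or stayed within 1.5 times a count. The overlap of odd and even peaks, the shared promoter genes and the Pvt1 region did so under every one of these. In the better-scoring 50% of each list, the promoter ratio of odd peaks was 1.60 and passed (permutation p = 0.0140), and 0 chromosome tests and 0 class tests passed, against 3 and 3; fewer peaks enter there. With promoters of 5000 bp the even promoter ratio was 1.17 (permutation p = 0.154). Without peaks over 50% soft-masked, 5 chromosome tests passed, where shuffled positions still included soft-masked sequence and so were not matched to the kept peaks. In that setting the shared minus unshared median fold of even peaks was 0.980 (permutation p = 0.0664). With protein-coding genes only, or positions matched in GC and repeat class, 0 class tests passed. The cause was not tested for these. Without peaks carrying a probe match or a recurring edge sequence, 117 peaks were left per list. The Pvt1 region then held 0 peaks in each list, which follows from its construction: the 8 peaks in the gene match a probe and the other 2 carry a recurring edge sequence. In that setting 0 chromosome tests and 1 class test passed, and the shared minus unshared fold of odd peaks was 0.977 (permutation p = 0.0680), with fewer peaks in each test. The overlap was then 34 of 117 even peaks (29.1%), against a shuffled mean of 0.0021 peaks, and the even promoter ratio was 2.74 (permutation p = 0.0020). No paired analysis was possible because the probe sets share only replicate number 1. Depth limits all lists: 1.08% of odd and 0.940% of even tags remained after duplicates were removed.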

Other observations

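Further shared peaks of 10 or more tags lay outside promoters and outside the genes of the fixed lists. Examples lay 159107 bp from Smad2 (11 odd and 10 even tags) and in an intron of Fhod3, a formin gene (10 tags in both lists). These peaks were picked by their height after the values were seen, and each had a recurring edge sequence.

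The tests in this part were chosen after the patterns were seen, except those on repeats and on probe hybridisation, which were set after the files were opened but before their outcomes were seen. The overlap of peaks unlike any probe was added after that, because both conditions set for hybridisation had been met. The condition set for repeats, a Fisher test in both lists, gave mixed results, and the overlap without repeats was used to decide after that. No biological explanation was tested, since the design holds no sample without Pvt1 or with unrelated probes. Contact of the RNA with chromatin stays open in part for each pattern. Of shared pairs, 88.5% started within 2 bp, against 1.70% of random overlaps. Of peaks with 4 or more tags, 71.4% had the length of consecutive starts, against 5.70% (odd) and 4.87% (even) in simulated independent starts. These values argue against independently sheared fragments as the whole source of those patterns. Copies of a molecule recovered by contact are not excluded by them.

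For peaks at the same places with odd and even probes, repeated sequence is argued against as the whole cause: without peaks over 50% soft-masked, 66.7% of even peaks were still shared, against 64.3% of all, although the share of such peaks among shared minus unshared peaks differed in sign between the lists (2.29 percentage points odd, Fisher exact p = 0.372, and -7.93 even, p = 0.0212). Probe hybridisation is argued against as the whole cause by the peaks unlike any probe. Of the even peaks no more similar to any probe than the median shuffled position, 250 of 411 (60.8%) overlapped such an odd peak. Of all even peaks, 64.3% overlapped an odd peak. The p of the former (permutation p = 0.0001) speaks only against random placement. The mean longest match to the probes of the own set exceeded that of shuffled positions by 0.292 bases in the odd list and 0.216 in the even list. That excess was under the bound of 0.5 bases set against hybridisation. Hybridisation stays open for a part of the peaks, since that excess also met the condition set for it. Its permutation p = 0.0099 for both was the smallest that 100 shuffles can give, with shuffled SDs of 0.0300 (odd) and 0.0349 (even) bases. The excess met both conditions and so does not decide. Of shared peaks, 55.0% odd and 54.9% even were no more similar to a probe than the median shuffled position, against 63.5% and 63.1% of shuffled positions. Without the peaks at Pvt1 the excess of the mean match was 0.204 and 0.132 bases. The odd mean was then 7.77 bases to the own set and 7.70 to the other, and the even mean 7.63 and 7.76. Both lists thus had the higher mean match to the odd probes. Shuffled positions did too, at 7.56 bases to the odd set (odd list) and 7.50 to the even set (even list). These means therefore do not show a preference of the lists for a set. Matches of at least 12 bases to the other set (17 odd and 10 even peaks) outnumbered those to the own set (11 and 9). With the Pvt1 peaks, a match of that length to either set stood at an edge of 3.33% of odd and 3.36% of even peaks. Random positions had one in 0.06% of cases. The starts of shared peaks differed by a median of 1 bp, as the same molecules in both libraries may give, while fragments sheared independently around a site would not be expected to start at the same base; this does not separate copied molecules from reads of a common sequence that align to the same places.

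Among peaks with 4 or more tags, most had their tags at neighbouring bases; peaks of 3 tags cannot show this. Over both lists, 71.4% of peaks with 4 or more tags had the exact length that consecutive starts give, against 5.70% in the odd list and 4.87% in the even list for simulated starts spread over 50 bp. This is what copies of one molecule with starts off by single bases may give, because the caller drops only tags at the same base. A candidate explanation that also met its prediction is that reads of one short sequence were aligned at many places: 66.3% of unshared even peaks had an edge sequence picked in unshared odd peaks, against 3.55% of random positions. The source of that sequence was not tested, and both explanations stay open together.

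The peaks at Pvt1 ended close to probe sites of either set. The right ends lay a median of 7 bp from the nearest probe 5′ end over both lists. This was above the 5 bp set for sequenced probe oligonucleotides and below the 20 bp set against them, so that prediction was not decided. The odd list alone was at 5 bp, and no right end in either list lay over 14 bp away. In both lists the median distance of left ends to the nearest probe 5′ end differed by 0 bp from the tag extension. Genomic fragments that extend on both sides of a contact would not be expected to end there. These values argue against such fragments as the whole source of the Pvt1 peaks, and sequenced probe oligonucleotides stay open. Probes of the other set were covered by a peak in 88.2% of cases, which is consistent with each library holding traces of the other probe set. DNA under the exons recovered by any probe would cover these sites too, but the peak ends argue against that as the whole cause. The odd peak over even probe 3 alone ended 1 bp from the 5′ end of that probe. The even peaks over odd probes 1, 4 and 5 alone ended 6, 3 and 1 bp away. Sheared DNA would not be expected to end at probes of the set that was not added.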
